A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

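Two-colour spotted arrays held 10752 spots, 4 per probe, for 2688 probes. Per the labels, RNA was DNA-free total RNA checked for integrity, the culture RNA carried Alexa 532 on 4 arrays and Alexa 647 on the other 4, and the standard reference carried the other dye. The deposited scanner tables give, per the file headers, the spot mean intensity and the local background median intensity of each spot in columns marked H and L for both dyes, with no normalization. What H and L stand for is not given in the sources used here. They were taken as a high and a low scan because the median L intensity lay far under the median H intensity on every array. The H columns were used. The L columns gave no usable ratio, since up to 65.2% of the Alexa 647 spots on an array were exactly 0 there. Scanner settings and image software are not given in the sources used here.

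The authors' deposited value table holds log10 ratios of Alexa 532 over Alexa 647. Its rows follow the order of spots across the slide and not the scanner's own order. On the brighter spots the values correlated with the raw log10 ratio at r = 0.545 to 0.918 in the slide order and 0.104 to 0.246 in the scanner order. With the intensity trend removed, r was 0.903 to 0.965 and the slope on the log10 ratio was about 1, so scale and direction are settled, and an intensity-dependent normalization was applied. Its method is not given in the sources used here. Column medians ran from 0.00444 to 0.117, so columns were not centred on the median, and 267 to 1873 spots per array are exactly 0. This table was used only as an alternative, with exact zeros left out and every array turned to culture over reference.

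Gene names came from the platform annotation that goes with the value table: 133 probes have 1 gene symbol, none has several and 2555 have none. All 133 symbols also occur in a RefSeq gene table of strain 91-R6, from which no coordinates were used. The annotation held here is partial, so most results are counts of probes.

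Intensities were corrected with normexp (offset 50), log2 ratios were normalized within each array by loess, the 4 spots of a probe were averaged and all ratios were turned to culture over reference. A channel counted as above background where at least 3 of the 4 spots exceeded 1.5 times the local background. The 1139 probes above background in at least 1 channel on at least 4 of the 8 arrays were tested, 97 of them named. Between 19.6% and 49.7% of spots lay under their local background, so log2 ratios are compressed and understate changes of dim probes. A channel with at least 2 spots of 60000 or more was called saturated. The S-layer gene csg was saturated in both channels on all 8 arrays and is given no fold, rpl12p was saturated on 4 arrays in each channel, and pyrB on 3 in the culture and 2 in the reference channel; gdhB, fer2, secY, glnA and ndk were saturated on 1 or 2 arrays in a channel. Where the culture or reference channel was not above background on any array, only a bound is given: the mean of the brighter side against, per array, the higher of the dim probe's own signal and the lowest signal above background, per channel after loess and Aquantile.

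The series describes 4 samples on 8 arrays as dye flips, and the labels do not say which arrays share an RNA. Before the data were examined, arrays with neighbouring array numbers, opposite dyes and one condition were taken as a pair and averaged, which leaves 2 RNA samples for light and 2 for darkness. The data give this pairing no support: across probes the paired arrays correlated at a median r of 0.0657, and the arrays paired the other way at 0.193. The other pairing was an alternative, and the count against the reference depends on it. Gene-specific dye effects were widespread: 402 probes, by coincidence the number called against the reference, passed a test of the dye term in a fit of the 8 arrays. The median absolute dye effect, culture in Alexa 647 minus culture in Alexa 532, was 0.20 (log2). The 2 orientations share this difference equally with opposite sign. It is therefore not on the same scale as the median absolute 0.09 for culture against reference. Of the 97 named genes 51 had opposite signs in the 2 orientations. Only means over both orientations are reported unless stated. Array dates are not used here.

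Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg adjusted p under 0.05), with light and dark as 2 group means. Light was tested against dark, their average and each alone against 0, and the lower- against the higher-numbered arrays with condition as a covariate. Gene lists with at least 3 measured genes (13 lists) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. A first set of lists was fixed before the data were examined; further lists, such as purine synthesis and secretion, were added after the gene names were seen. Named genes followed a rule fixed beforehand: up to 12 with a symbol in each direction by size among those past the threshold whose RNA samples all moved one way (for light against dark, whose conditions did not overlap), filled with genes not past it, plus the knocked-out genes and up to 4 members of each list. Other genes named as past the threshold, such as cheA, psmB, proS and lysS, are list members.

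The fit was tested on simulated data with 200 of 1139 probes changed. For light against dark it recovered 0.0%, 85.0% and 99.0% of changes of 1.19-, 1.41- and 2-fold, and for culture against reference 78.5%, 98.0% and 100.0%. False calls made up at most 8.33% of the calls. The simulated RNA samples varied independently, were paired as assumed here, and met a reference without spread of its own. These points are not established for the data, so the rates hold for the simulated setting only. Alternatives covered background correction, normalization, dim probes, the deposited values, pairing, dye orientation, variance prior, thresholds and left-out samples or arrays. Plain background subtraction, the joint change of background and normalization, and a fit with both blocks were added after seeing the data.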

Results

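Transcript levels were measured on 8 spotted DNA arrays of Halobacterium salinarum NRC-1, an extremely halophilic archaeon that swims towards or away from light and can use light as an energy source. Each array paired RNA from a culture whose strain is labelled as lacking ura3 (pyrF, the last step of UMP synthesis) and phoR with one standard mid-log reference RNA of NRC-1. The cultures grew in rich medium to mid-log phase, 50 mL in a 125 mL flask shaken at 210 rpm, in light or in darkness, and every label describes high oxygen. There were 4 arrays for light and 4 for darkness, read as 2 RNA samples per condition, each on 2 arrays with exchanged dyes. Whether the label means 1 strain lacking both genes or more than 1 strain is not given in the sources used here, so the RNA samples averaged may differ in strain. Nothing in the labels says that the 2 RNA samples of a condition came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Between 932 and 1389 of the 2688 probes were above background in at least 1 channel of an array. The number of arrays limits the precision.

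The knocked-out genes come first, as a check of the labels. The probe for pyrF was not above background on any of the 8 arrays in either channel, with a signal of 0.615 to 0.932 times the local background in the culture channel and 0.867 to 1.20 times in the reference channel. No fold can be given for it. None of the 133 named probes carries the symbol phoR, so the second deletion was not analysed here by name, and the labels were not checked by either gene.

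The first comparison asked whether light changed transcript levels. In the light samples the highest differences over darkness among named genes whose samples did not overlap between the conditions were those of panB, a coenzyme A synthesis enzyme, at a log2 difference of 0.26 ± 0.09 (SE), folP, a folate synthesis enzyme, at 0.20 ± 0.08, and the chaperone gene dnaK at 0.15 ± 0.08. The lowest were those of pan1, a proteasome-activating ATPase, at -0.25 ± 0.10, carA, the small subunit of carbamoyl-phosphate synthase, at -0.16 ± 0.08, and sop1, the phototaxis receptor sensory rhodopsin I, at -0.16 ± 0.08. None of these passed limma's moderated test over 1139 probes (adjusted p = 0.938 for each of the 6; 2 RNA samples per condition). For panB the mean log2 ratios to the reference were 0.02 ± 0.01 (SD, n = 2) in light and -0.24 ± 0.17 in darkness, and for sop1 they were 0.22 ± 0.08 and 0.38 ± 0.03.

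Other named genes whose 2 light samples both lay above the 2 dark samples were glyA (0.15), the chemotaxis genes cheR (0.14) and cheY (0.10), proS (0.13), gyrA (0.11), purF (0.11), gatA (0.09), ileS (0.05) and cmk (0.04), all as log2 differences that did not pass. Those with both dark samples higher were hisS (-0.14), rpmC (-0.13), pheS (-0.09), aspS (-0.08), rimI (-0.08), purD (-0.08), lysS (-0.08), cobN (-0.07) and hisF (-0.07), which did not pass either. In total 13 named genes separated in each direction, and 34.2% of all probes tested did so in either direction, against 33.3% by chance for 2 samples against 2.

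**Figure D1:**
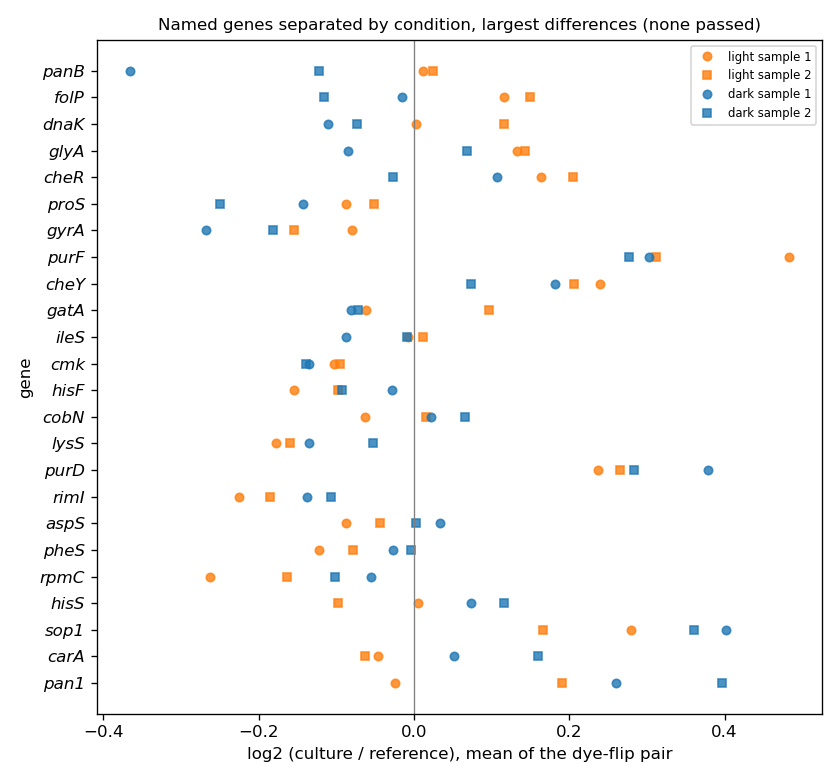
Log2 ratio of culture to reference (x axis) in each RNA sample for the 24 named genes with the largest light-dark differences among those whose conditions did not overlap (y axis); orange marks light, blue marks darkness, and each point is the mean of 2 dye-flipped arrays. The 2 colours separate for each gene by the rule that chose them, panB at the top by 0.26 and pan1 at the bottom by -0.25, and none of the differences passed.

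By group, the light receptors and their transducers showed no change that passed between light and darkness: sop1 is given above, htr1, the transducer of sensory rhodopsin I, was at -0.06, htr2 at 0.01 and sop2, sensory rhodopsin II, at -0.01. The arginine fermentation genes arcA and arcC were at -0.02 and -0.01, and phoU, the only named phosphate gene, at 0.08 ± 0.16 (SE). Across the 13 lists with at least 3 measured genes the smallest camera adjusted p was 0.922, and 0.984 with an estimated correlation.

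Over all 1139 probes 0 passed at an adjusted p of 0.05 in limma, 51 had an unadjusted p under 0.05, and fits of the 8 single arrays, independent or with the dye-flip pair as a random block, also gave 0. The median half-width of the 95% confidence interval was 0.18 on the log2 scale. In simulated data with independent samples 85.0% of 1.41-fold changes but 0.0% of 1.19-fold changes were recovered. With the lower- and the higher-numbered arrays as blocks, which pair light with dark samples, 12 probes passed, 4 higher and 8 lower in light and none with a symbol, in a fit with 1 residual degree of freedom and the same standard error of 0.0892 for every probe. Leaving out 1 dark RNA sample also gave calls, but such a fit has 1 dark sample and 1 residual degree of freedom. Leaving out 1 light RNA sample gave no calls.

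The second comparison set the knockout cultures, light and dark together, against the reference strain's RNA. Purine synthesis genes were higher in the cultures: purF, the first committed step, was 1.27-fold higher (log2 0.34 ± 0.09 SD, n = 4 RNA samples; limma adjusted p = 0.00134), purD 1.22-fold (0.29 ± 0.06), purM 1.18-fold (0.24 ± 0.02) and purE 1.18-fold (0.24 ± 0.09). Both measured genes of arginine fermentation rose, arcC (carbamate kinase) 1.25-fold and arcA (arginine deiminase) 1.22-fold, as did sop1 (1.23-fold) with its transducer htr1 (1.16-fold). Among the genes that fell, infB, a translation initiation factor, was 1.30-fold lower (log2 -0.38 ± 0.14), hemA, the entry to haem and cobalamin synthesis, 1.23-fold (-0.30 ± 0.09), cbiT, of cobalamin synthesis, 1.22-fold (-0.29 ± 0.15), and carB, the large subunit of carbamoyl-phosphate synthase, 1.20-fold (-0.26 ± 0.13). Each of these genes lay on the same side of the reference in all 4 RNA samples, which the rule that chose them requires. Several of these means rest mainly on 1 dye orientation. With the culture in Alexa 532 and in Alexa 647 the log2 ratios were 0.59 and 0.10 for purF, 0.06 and 0.50 for arcA, 0.08 and 0.52 for sop1, 0.41 and 0.18 for purD, 0.12 and 0.36 for purM, 0.21 and 0.44 for arcC, and 0.01 and -0.61 for hemA.

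Of the 6 purine synthesis genes measured 4 rose and 2 did not pass, 5 when adjusted over the list alone, and the list moved up against other genes (camera adjusted p = 0.036 over 13 lists). The adjusted p was 0.63 with an estimated correlation. This list was drawn up once the array's gene names were known and before their test values were seen. On the flagella and chemotaxis list 6 genes were measured, all of them chemotaxis genes or transducers and none a flagella gene. Of these 4 rose (5 adjusted over the list alone). They were htr6, a transducer, at 0.25 ± 0.04 (SE, limma adjusted p = 0.00383), cheB at 0.18 ± 0.04 (0.02 and 0.34 in Alexa 532 and 647), cheY at 0.18 ± 0.04 and cheA at 0.14 ± 0.04. The list itself stood at a camera adjusted p of 0.054, or 0.63 with an estimated correlation. Of the 4 genes measured on the purple membrane and retinal protein list, all of them sensory rhodopsins or their transducers, 2 rose, with sop2 at 0.11 and htr2 at -0.04 not past the test (camera adjusted p = 0.23). The 2 arginine fermentation genes both rose and passed also over the list alone, but 2 genes are too few for a list test here.

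In the TCA cycle sucC, of succinyl-CoA synthetase, fell (log2 -0.20 ± 0.04 SE, adjusted p = 0.00802), and the other 4 of 5 genes did not pass but were all below 0, with icd at -0.12 and citZ at -0.12 (camera adjusted p = 0.11). Of the 4 cobalamin synthesis genes 2 fell, cbiT and cbiG (-0.19; -0.34 and -0.04 in Alexa 532 and 647), while cbiQ was at 0.05 and cobN at 0.01. Among 4 pyrimidine genes carB fell, and carA (0.03), pyrI (0.06) and pyrB (0.01, saturated on 3 arrays in the culture and 2 in the reference channel) did not pass; the list's median was 0.02 and its mean -0.04. Of 9 aminoacyl-tRNA synthetase genes proS (-0.13) and lysS (-0.13, with -0.03 and -0.23 in Alexa 532 and 647) fell. Their list was set to hold translation factors too, but no such gene was measured on it. Of 5 chaperone and protease genes pan1 rose (0.21 ± 0.05 SE) and psmB, a proteasome subunit, fell (-0.12 ± 0.04). The call held in 15 of 27 alternative settings for pan1 and in 6 of 28 for psmB. The phosphate gene phoU was at -0.13 ± 0.08 (adjusted p = 0.253).

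The remaining genes named by rank were moaC, of molybdenum cofactor synthesis, which rose (0.25; 0.46 and 0.04 in Alexa 532 and 647), and thiL (-0.20), speB (-0.19), cca (-0.19; -0.09 and -0.29), pheA (-0.18), gyrA (-0.17; -0.31 and -0.03) and rimI (-0.16), which fell. They cover thiamine and polyamine synthesis, tRNA end repair, phenylalanine synthesis, DNA supercoiling and protein acetylation. For thiL the culture channel was above background on 2 of 8 arrays, for infB and cca on 4.

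**Figure D2:**
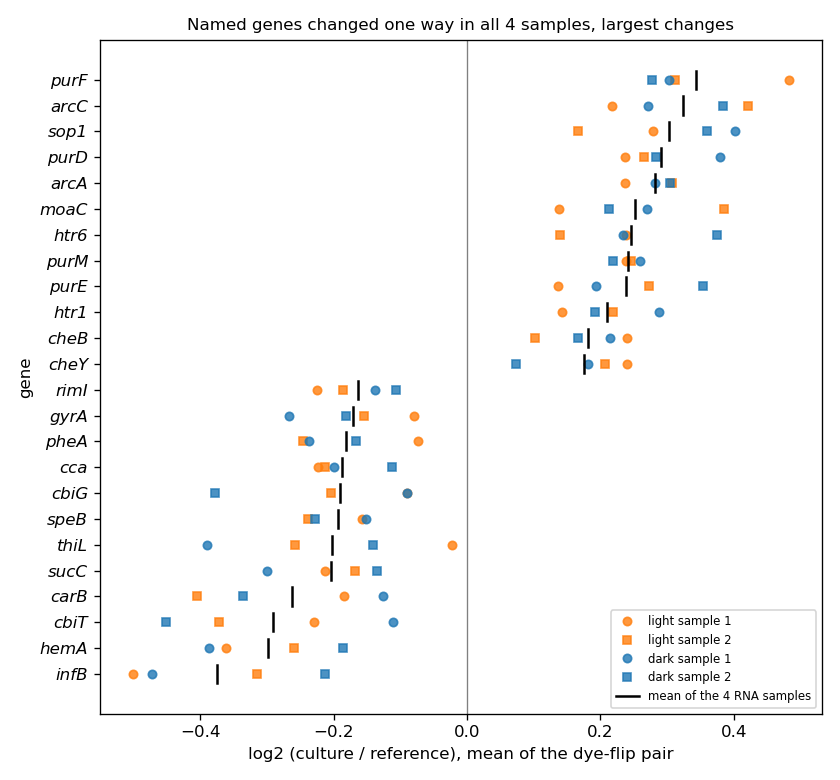
Log2 ratio of culture to reference (x axis) in each of the 4 RNA samples for the 24 named genes with the largest changes in one direction in all 4 (y axis); points are means of 2 dye-flipped arrays and the bar is the mean of the 4. All 4 samples of each gene lie on one side of 0 by the rule that chose them, from purF at 0.34 to infB at -0.38.

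In total 402 of 1139 probes passed, 221 higher and 181 lower, and 34 of the 97 named genes, 15 higher and 19 lower. Only 5 passed with a fitted change of at least 2-fold, none of them named. The probe probe_3717 rose 2.03-fold (log2 1.02 ± 0.25 SD, n = 4), followed among measured probes by probe_4007 at 1.42-fold. The probes probe_4433 and probe_5161 were not well above background in the culture channel on any array. As bounds, they were at least 1.49-fold and at least 1.12-fold lower than the reference. The limma adjusted p of 0.000605 and 2.08e-05 belong to their fitted ratios, and the bounds were not tested. The reference channel was above background on 4 arrays for probe_4433 and on 6 for probe_5161. In 2 other probes the fall was 1.36 and 1.19 on the log2 scale.

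The reference is 1 RNA preparation, so these tests leave out its own spread, and strain, culture and growth conditions can all differ between the 2 sides. With the arrays of each condition paired the other way 186 probes passed, and leaving out 1 array gave 170 to 272. Plain background subtraction gave 0 (smallest limma adjusted p = 0.0630). The count also changed widely with the RNA sample left out, in fits that leave 1 sample in a condition.

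Each condition was also set against the reference alone. In light 142 probes passed, 80 higher and 62 lower. The 14 named among them were purF (0.40), arcC (0.32), arcA (0.27), moaC (0.26), purD (0.25), purM (0.24), sop1 (0.22) and cheY (0.22), which rose, and infB (-0.41), hemA (-0.31), carB (-0.29), cca (-0.22), rpmC (-0.21) and rimI (-0.21), which fell. In darkness 253 probes passed, 132 higher and 121 lower. The named ones were sop1 (0.38), purD (0.33), pan1 (0.33), arcC (0.33), htr6 (0.30), arcA (0.29), purF (0.29), purE (0.27), moaC (0.24), htr1 (0.24), purM (0.24) and cheB (0.19), which rose, and infB (-0.34), hemA (-0.29), cbiT (-0.28), thiL (-0.27), panB (-0.24), gyrA (-0.22), sucC (-0.22), srp19 (-0.22), pheA (-0.20), proS (-0.20) and speB (-0.19), which fell. A gene past the threshold in 1 condition alone is not shown to differ between them, since the direct test passed 0 probes. With median centring 54 probes passed in light and 150 in darkness, and on the arrays with the culture in Alexa 647 alone 2 and 25, and on those with Alexa 532 alone 120 and 209.

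The lists for purine synthesis and for flagella and chemotaxis both moved up in light (camera adjusted p = 0.019 and 0.040, each 0.63 with an estimated correlation), with 3 of 6 and 1 of 6 genes past the test. The second list held no measured flagella gene. In darkness 4 of 6 and 2 of 6 genes rose, and the lists stood at 0.065 and 0.12.

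**Figure D3:**
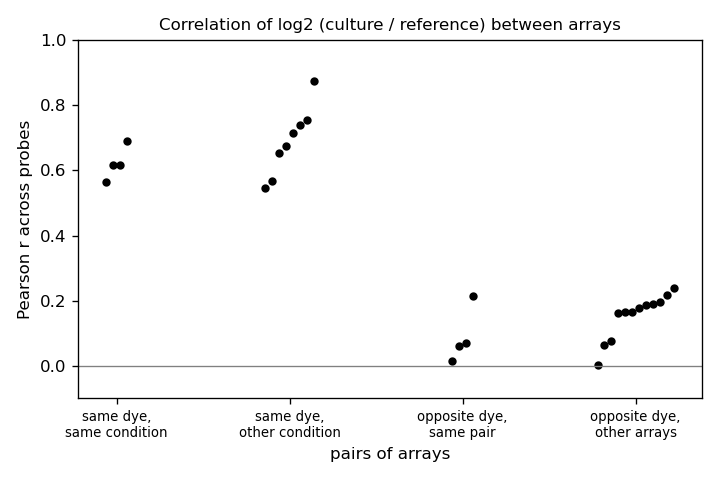
Pearson r of the log2 ratios of culture to reference across 1139 probes (y axis) for each pair of the 8 arrays, grouped by dye orientation and by condition or dye-flip pair (x axis); 1 point is 1 pair of arrays, and probes are not independent replicates. Arrays of one orientation reach 0.55 to 0.87 and arrays of opposite orientation 0.004 to 0.24.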

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

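The array-number split and the test of gene lists under lower oxygen were set before the data were examined, and which lists that test can use and the tests of dye orientation and of the variance estimate were chosen only after the result was seen. Among 104 groups of 4 arrays (named genes and array summaries), 6 held an array far from the other 3, against 5.2 expected by chance at about 1 in 20. That rate assumes 4 values from the same distribution, but each group mixes both dye orientations, so it is only a rough guide. For phoU, the array light 2 stood at a log2 ratio of -0.66 with the other light arrays between 0.04 and 0.14, and the array dark 2 at -0.66 with the others between -0.02 and 0.01. For glyA the array dark 2 stood at -0.31, for infB the array dark 4 at -0.00574 and for pan1 the array dark 1 at 0.14, against 0.06 to 0.14, -0.49 to -0.42 and 0.38 to 0.40 on the others. The median reference signal of the array dark 3 was 3192, against 2040 to 2236 on the other dark arrays.

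Both outlying phoU arrays carry lower numbers and the culture in Alexa 647, and phoU is among 22 probes that differed between the higher- and the lower-numbered arrays (19 higher, 3 lower; phoU 0.40, adjusted p = 0.00163; hisG 0.32, adjusted p = 0.0298, both in limma). Different strains, cultures or RNA preparations were not tested and stay open, as does lower oxygen in one set of cultures. The rule set beforehand counted absolute medians under 0.25 in at least 2 of the 3 lists against lower oxygen. The medians were -0.0011 for the purple membrane list and 0.10 over 2 genes for arginine fermentation, so that rule came out against it. However, only 1 of the 3 lists, arginine fermentation, held a measured oxygen-linked gene. No gas vesicle gene is named here, and the purple membrane list was measured only through sensory rhodopsins and their transducers. The rule therefore cannot decide here. For 12 of the 22 probes the difference was opposite or under 0.25 times as large in the weaker dye orientation, so one orientation may carry it for those, as for phoU (0.06 in Alexa 532, 0.74 in Alexa 647). The largest difference, that of probe_4433 (0.83), was alike in both orientations (0.68 in Alexa 532, 0.98 in Alexa 647). Its culture channel was not above background on any array. The 7 probes alike in both orientations, probe_4433 among them, all went the same way in all 4 pairs of a lower- and a higher-numbered array. They were picked on those differences, so for them it stays open. The fit has 1 residual degree of freedom and gives every probe the same standard error, and 2 of the 22 calls remained with the 8 arrays entered singly and the pair as a random block, which is consistent with too small a variance estimate.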

How the results depend on the processing

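Plain background subtraction, no background subtraction together with median centring, and the replicate block together with the random block were chosen after seeing the data; the other alternatives were set beforehand. Against the reference, 402 probes in the fit reported became 412 without background subtraction, 290 with median centring (171 higher, 119 lower), 351 of 767 with only probes above background on every array, 453 with the deposited values, 469 with 8 arrays and the pair as a random block, 358 as independent arrays, 356 on Alexa 532 arrays (156 higher, 200 lower; 183 of the 402 called again and 338 in the same direction), 317 on Alexa 647 arrays (191 higher, 126 lower; 206 called again and 388 in the same direction), 407 with a trended prior, 400 with scaling between arrays, 535 at an adjusted p under 0.10, and 369 with no background subtraction and median centring (257 higher, 112 lower). It fell to 155 (65 higher, 90 lower) without the filter on dim probes, where 2688 were tested, to 186 with crossed pairs, to 5 with an absolute log2 of at least 1 and to 0 with plain subtraction, where 392 of 397 kept their direction. Leaving out 1 array or RNA sample gave 54 to 408, and for a condition left with 1 sample that sample is assumed to vary like the others. Light against reference gave 54 with median centring, 2 on Alexa 647 and 120 on Alexa 532 arrays, and dark against reference 150, 25 and 209. Of 41 called genes and probes followed singly against the reference, 16 lost the call with crossed pairs and 25 without the filter on dim probes. With plain subtraction all 39 measured lost it. The call held in 6 of 28 alternatives for psmB, 8 for cmk and rpl12p, and 9 for proS and srp19. It held in 25 of 28 for purF and arcC and in 22 of 27 for infB.

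Light against dark called 0 probes, and 0 to 13 when leaving out 1 array or RNA sample. A replicate block for the lower- and higher-numbered arrays, which pairs light with dark samples, gave 12 (smallest adjusted p 0.00177, 1 residual degree of freedom). It is the fit of the array-number split, with the same standard error for every probe, and with this block kept in a fit of 8 arrays with the dye-flip pair as a random block the count was 0. Light and dark samples of the same number deviated together (r = 0.215 across probes), and light and dark arrays of the same dye orientation correlated at a median of 0.747 in the same set of numbers, 0.610 across the sets and 0.617 within a condition. This is a hint from the data that numbers pair the samples, which the labels do not say. The 22 probes of the array-number split became 1 without background subtraction, 3 with median centring, 0 without the filter, 11 with only probes above background on every array, 0 with the deposited values, 2 with the random block, 1 as independent arrays, 11 on Alexa 532 arrays, 83 on Alexa 647 arrays, 2 with scaling, 0 at an absolute log2 of at least 1, 0 with plain subtraction, 0 with no background subtraction and median centring, and 0 to 2 when leaving out 1 array. They became 29 with a trended and robust prior, which kept 20 of the 22, and 33 at an adjusted p under 0.10. Leaving out an RNA sample could not be fitted for this split. Crossed pairs each join a lower- and a higher-numbered array, so they leave no such split; the contrast they give, dye orientation crossed with array number, called 190 probes (24 higher, 166 lower); 8 of the 22 kept their direction and 0 of those were called.

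Against the reference 1 gene list shifted, 0 with an estimated correlation and 2 with fry; in light 2, then 0 and 1; in darkness 0, then 2 with fry and 1 with median centring.

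In that other contrast phoU stood at -0.34. Reversed log2 ratios on Alexa 532 arrays were hemA 0.0137, rpl12p 0.12 and srp19 0.21 against the reference, sop1 -0.0543 and hemA 0.0294 in light, and srp19 0.13 in darkness. On Alexa 647 arrays they were cmk -0.0159 and hisF 0.0259 for light against dark, and moaC -0.0450 in darkness against the reference. For light against dark, plain subtraction gave pan1 0.24, and no background subtraction with median centring gave gatA -0.0307 and ileS -0.00419. Leaving out 1 array moved light against dark from -0.0860 to 0.30 for purF, -0.0332 to 0.13 for ileS, -0.0272 to 0.10 for cmk, -0.34 to 0.0269 for sop1, -0.29 to 0.12 for pheS, -0.195 to 0.0271 for aspS, -0.16 to 0.00309 for purD, -0.15 to 0.00287 for lysS, -0.17 to 0.0337 for cobN and -0.15 to 0.0162 for hisF. The cause was not tested, except that fewer arrays, more probes or a higher threshold themselves change a count. Dim spots limit what can be measured, since 19.6% to 49.7% of spots lay under their local background.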

Other observations

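The tests of the 4 low probes and of dye bias were chosen only after the results were seen. The gene list tests, the fits of 1 dye orientation and the count of splits were set beforehand, but the lists for secretion, cofactors, histidine, glutamate, central carbon, aromatic amino acids, nucleotide kinases and DNA topology were added once the gene names were seen. The list of secretion and ribosome-associated proteins had 7 measured genes: infB, srp19, rpmC, rpl12p, gatA, secF and secY. Of these 4 fell against the reference. They were infB, srp19 (log2 -0.16 ± 0.04 SE), a signal recognition particle protein, rpmC (-0.15 ± 0.04), ribosomal protein L29, and rpl12p (-0.12 ± 0.04), which was saturated on 4 arrays in each channel. The list stood at a camera adjusted p of 0.11, or 0.63 with an estimated correlation. On the arrays with the culture in Alexa 532 alone srp19 was at 0.21 and rpl12p at 0.12, so both falls came from the other orientation.

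Cofactor genes went both ways, with moaC up and hemA and thiL down among 6 measured (camera adjusted p = 0.58). The 3 histidine synthesis genes (median -0.09, camera adjusted p = 0.42), the 4 glutamate and glutamine genes (0.02, 0.72) and the 4 central carbon genes (-0.01, 0.81) held no call. For cobalamin synthesis, aminoacyl-tRNA synthetases, chaperones and pyrimidines the camera adjusted p was 0.42, 0.41, 0.58 and 0.72. In lists too small to test, pheA, cmk (-0.12) and gyrA fell, and the nuoL, sdhC, dpsA, msrA, uvrB and mvk probes did not pass. No gas vesicle, ATP synthase, RNA polymerase, metal transport or transposase gene is named here. No histidine degradation gene was above background on enough arrays to be tested.

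Of the 4 probes with a fitted fall of at least 2-fold against the reference, 2 are measured and 2 have only the bounds given above. A dye bias that is the same on every array cancels in the mean by which these 4 were picked. They lay below the reference on all 8 arrays, but that choice makes this likely, so it is no separate test. Their highest mean in 1 orientation was -1.13 (probe_1547, Alexa 532), so neither orientation alone carried the falls. The background correction of dim spots is argued against, since without background subtraction all 4 passed with log2 ratios no higher than -0.97. Deletion of the gene under the probe may account for 1 of the 2 that had a culture signal above background on 0 of 8 arrays. It cannot account for both unless phoR has several probes or pyrF, the other deleted gene, has another probe besides its named one. Neither of the 2 has a gene name here, so this stays open. The other 2 were set apart because their culture channel was above background on 4 of 8 arrays. This count formed the group, so it is no separate test of deletion. Signal at the probe of a deleted gene would need another transcript to bind it, RNA samples that keep the gene, or a probe outside the deleted part. A difference between the strains or cultures other than the deletions stays untested.

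A gene-specific dye bias that is the same on every array cancels in the means against the reference, which hold both orientations equally. It turns its sign with the orientation, and arrays of one orientation correlated at 0.55 or more, so bias alone would give a clearly negative r between the orientations. Across the 1134 probes without those beyond 2-fold, r was 0.0232 in light and 0.0450 in darkness, which argues against bias as the whole cause of the differences on single arrays. Genes are not independent replicates. A bias that differs between the lower- and the higher-numbered arrays is taken up with the splits below. One that differs between single arrays was not tested.

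For light against dark, the real split of the 8 arrays into 4 and 4 called 0 probes (arrays as independent with a dye term), so all 35 splits give at least as many by construction and their count says nothing about chance. The highest other split gave 75, and it is the one that crosses dye orientation with the lower- and higher-numbered arrays. With the pairing used here, it measures a dye effect that differs between these sets of arrays. With the other pairing it would measure a difference between RNA samples of a condition, so the split cannot tell which. The split by dye orientation itself, fitted without a dye term, called 430.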
